A study of Mus musculus with 19 samples.

How the data were processed

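RNA was measured by sequencing in 19 whole tumours. The tumours were grown from Met1, a transplantable mouse mammary tumour line, in mice that were given extracellular vesicles from neutrophils. The neutrophils had been treated with the solvent DMSO (9 tumours) or with 27-hydroxycholesterol (27HC), a cholesterol metabolite that binds oestrogen receptors and liver X receptors (10 tumours). Per the labels' protocols, tumours were frozen on dry ice, RNA was extracted with Trizol, and stranded paired-end libraries of poly(A) RNA were sequenced on an Illumina HiSeq instrument. The dose, route and time of the vesicle treatment and the site of implantation are not given in the sources used here. The labels do not say whether each tumour came from a separate mouse or whether mice shared cages or sequencing runs. The p-values therefore measure the spread between these samples.

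The deposited table holds expected counts for 26796 genes with Ensembl identifiers in 19 columns, and each column was matched to 1 sample by its title. The DMSO columns carry the titles, and the 27HC columns carry them without the leading 27. The submitters' processing notes name kallisto 0.44.0, edgeR, limma and the mouse build GRCm38, without saying what each was used for. How the estimated counts were summed from transcripts to genes, the annotation release and any filter are not given in the sources used here. The deposited expected counts were fractional, were at least 0, and summed per column to a whole number within 7.5e-09. No gene had a value of 0 in every column. Estimated counts assign reads shared by near-identical transcripts by a model, so values of pseudogenes, histocompatibility genes, globins and ribosomal protein genes carry that uncertainty. Totals ranged from 28139419 to 41179056 expected counts per sample, and values were rounded to whole numbers before testing. Gene symbols were found for 26290 identifiers and were missing for 506. Coordinates, gene types and transcript GC content were taken from GENCODE M21 on GRCm38. Of the genes in the table, 20076 are protein coding and 5823 are pseudogenes.

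Samples were grouped by the treatment label. Each title also carries a pair of numbers, of which the first is 1 or 2 and has no stated meaning: 5 DMSO and 5 27HC tumours carry a 1, and 4 DMSO and 5 27HC tumours carry a 2. This number was left out of the fitted model and used in alternatives and in an interaction test. The comparison of 27HC with DMSO was fitted with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, after TMM normalization and the default filter on low counts (filterByExpr), which kept 15629 genes and left out 11167. Fold changes are 27HC over DMSO on the log2 scale, with standard errors from the F statistic and 17 residual degrees of freedom plus those added by the prior. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given in CPM, counts scaled by the normalized library size, as mean ± SD over 9 DMSO and 10 27HC tumours. Scores use log2 CPM with a prior count of 2.

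Gene lists were fixed before the data were examined: pathways linked to cholesterol, oestrogen, tumour growth, inflammation and stress, and markers of the other cell types that a whole tumour can hold. Of these, 34 had at least 5 tested genes, including the mitochondrially encoded and ribosomal protein genes taken by symbol. The lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then with a correlation estimated per list, and with fry. Each list also had a score per tumour, the mean z-score of its members, compared between groups by a two-sided exact permutation test over all 92378 regroupings. The smallest p this test can give is 1.1e-05. The rule for named genes was also fixed in advance. It took genes past the threshold by fold change, or failing that the 5 with the smallest unadjusted p per direction among genes of at least 1 log2 CPM, which are said not to have passed. It added up to 4 members with the smallest p per list, and 20 genes named whatever their values. Only part of the genes this rule takes are named, 3 were left out of the results for single genes and are not reported here, and the lists were tested with all their members.

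Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter, a filter at 1 log2 CPM, sample quality weights, the full title number as a block, the first title number as a covariate or a random block, each first number alone, other thresholds, and leaving out each tumour in turn. Added after seeing the data were a correction for GC content per library (loess, span 0.3), a fit without 5 libraries with low GC content, the skeletal muscle score as covariate, and 3 surrogate variables from sva 3.50.0. Pairwise chi-square tests found no duplicated library: the lowest value between tumours of 1 group was 42.3 per degree of freedom.

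The fit was tested on simulated counts drawn from the means, the spread per gene and the library sizes of these samples. Each gene was drawn independently, so structure shared between genes was absent. The changed genes were picked above a lower limit of mean level. The rates that follow hold for that setting and can differ in the real tumours. In the simulation of 27HC against DMSO with 15442 genes tested, it recovered 25.4% of genes changed 1.5-fold (17 of 67), 68.7% of those changed 2-fold (46 of 67) and 93.9% of those changed 4-fold (62 of 66). It called 5 of 15211 unchanged genes. Tables were read with Python 3.11.15 and pandas 2.3.3.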

Results

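Gene expression was measured in 19 Met1 mammary tumours from mice given extracellular vesicles, the membrane particles that cells shed. The comparison asks how tumours exposed to vesicles from 27HC-treated neutrophils (n = 10) differ from tumours exposed to vesicles from DMSO-treated neutrophils (n = 9). Total expected counts ranged from 28139419 to 41179056 per tumour, and the groups differed in this total with a two-sided exact permutation p of 0.0557. Between 18614 and 21064 genes had at least 1 count in a tumour.

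No gene passed the threshold between the groups. Among genes with a mean of at least 1 log2 CPM, those with the smallest unadjusted p on the higher side were Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, and Per2, a core gene of the circadian clock. On the lower side they were Bbs9, a subunit of a ciliary transport complex, and Plau, the urokinase plasminogen activator. In the edgeR quasi-likelihood test 0 of 15629 genes passed, 0 higher and 0 lower, and the smallest adjusted p was 0.838. At an unadjusted p under 0.05 there were 354 genes, 201 higher and 153 lower with 27HC, fewer than the 781 that tests without any difference would give on average. limma-voom also called 0 genes, and DESeq2 called 2, Tsc22d3 and Bpifa2.

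Tsc22d3 (ENSMUSG00000031431, GRCm38 chromosome X, 140539528 to 140600659) had 40.3 ± 9.18 CPM (SD, n = 9) with DMSO and 69.6 ± 15.9 CPM (SD, n = 10) with 27HC. Its log2 fold change was 0.79 (SE 0.16), and all 10 27HC tumours lay above the DMSO median. The edgeR adjusted p was 0.838, and DESeq2 gave a log2 fold change of 0.80 with an adjusted p of 0.0217. Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) had 30.5 ± 4.78 CPM (SD, n = 9) and 46.0 ± 11.7 CPM (SD, n = 10), a log2 fold change of 0.60 (SE 0.15). The next genes on the higher side, by unadjusted p, were Prrt1, with a log2 fold change of 0.49 (SE 0.13), the processed pseudogene Gm10163, with 0.72 (SE 0.20), and the myosin light chain gene Myl4, with 1.93 (SE 0.55). Myl4 was high in 27HC replicates 1_2, 1_3, 1_5 and 2_3, which also had the highest skeletal muscle scores of their group, and its log2 fold change was 1.18 without 27HC replicate 1_5 and 0.62 without the 5 libraries of low GC content. On the lower side Bbs9 (ENSMUSG00000035919, chromosome 9, 22475715 to 22888280) had a log2 fold change of -0.40 (SE 0.11) and Plau (ENSMUSG00000021822, chromosome 14, 20836660 to 20843385) one of -0.51 (SE 0.15). Pdk1, a kinase that inhibits pyruvate dehydrogenase, followed with -0.37 (SE 0.11), the mitochondrial ribosomal gene Mrpl9 with -0.32 (SE 0.09) and the mitotic kinesin gene Kif20a with -0.36 (SE 0.11). The adjusted p of each of these genes other than Tsc22d3 was 1 in edgeR's test.

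The other DESeq2 call, Bpifa2, encodes a secretory protein of the salivary glands. It was lower with 27HC (log2 fold change -2.33, DESeq2 adjusted p = 0.0217), and 99.9% of its reads came from 1 library, DMSO replicate 1_5. At least 10 expected counts of it were found in 8 of 9 DMSO libraries and in 1 of 10 27HC libraries. Apart from DMSO replicate 1_5, with 197017, these were low counts: 5.6 to 42.7 in the other DMSO libraries. The highest of the remaining tumours was 27HC replicate 1_4, with 74.3, and the other 27HC libraries had at most 5.8. DESeq2 was run with its defaults, which replace outlying counts in groups of this size. Its fold change therefore need not include the counts of DMSO replicate 1_5. In edgeR's test, which kept all counts, the log2 fold change of Bpifa2 was -10.59 (SE 2.31) with an adjusted p of 0.880. The unprocessed pseudogene Gm29216 had 9.23 (SE 1.99) and the same adjusted p, and the amylase gene Amy1 had -7.86 (SE 1.84). Like Bpifa2, both had smaller unadjusted p than Per2 but a mean of log2 CPM over the tumours below the limit for naming. Averaged as CPM they were not low. Gm29216 had 215.2 ± 455.4 CPM with 27HC, and Amy1 175.8 ± 524.9 and Bpifa2 442.0 ± 1324 CPM with DMSO. Gm29216 had 38472 and 22896 expected counts in 27HC replicates 1_5 and 2_4 and at most 120.0 in any other tumour. These genes were named after their values were seen.

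**Figure D1:**
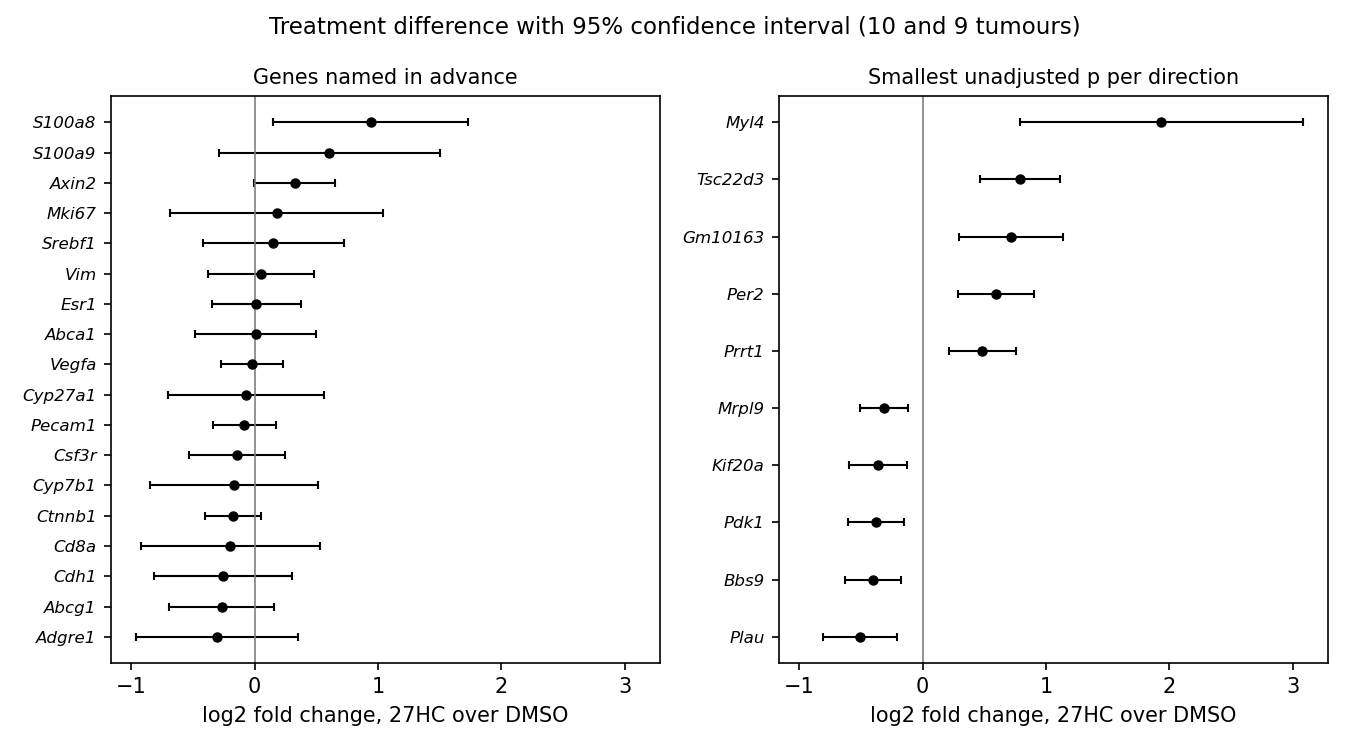
Log2 fold change of 27HC over DMSO (horizontal axis) for 18 genes named in advance (left) and for the 5 genes per direction with the smallest unadjusted p among those with a mean of at least 1 log2 CPM (right). Points are the edgeR estimates and bars are 95% confidence intervals over 10 and 9 tumours. Intervals that leave out 0 are not adjusted for the 15629 genes tested, of which 0 passed.

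The precision differed between genes. The 95% confidence interval of the fold change lay within 2-fold in either direction for 15 of 18 genes named in advance, and within 1.5-fold for 7 of them. Of the 18, the intervals of S100a8, S100a9 and Mki67 reached past a 2-fold higher level and excluded a 2-fold lower one. Leaving out 1 tumour moved log2 fold changes by over 1.5 times in at least 1 of 19 fits for 103 of 156 named genes. The sign turned for 24, none of which passed. Such a ratio moves easily where the value is near 0: Abca1, at 0.009 (SE 0.23), ran from -0.113 to 0.115. Over all 15629 genes, 86.3% of the intervals lay within 2-fold and 53.2% within 1.5-fold.

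Genes of the sterol pathways that respond to oxysterols did not pass. Abca1 and Abcg1, cholesterol exporters induced by liver X receptors, had log2 fold changes of 0.01 (SE 0.23) and -0.27 (SE 0.20). Srebf1, a regulator of fatty acid synthesis, had 0.15 (SE 0.28). Of the 16 liver X receptor targets tested, 7 had a fold change above 0 and 9 below, with a median log2 fold change of -0.07. Cyp51, a sterol demethylase of cholesterol synthesis, had a log2 fold change of -0.37 (SE 0.13). In the cholesterol synthesis list 16 of 23 genes were below 0, with a median of -0.05. Among 8 oxysterol metabolism genes the median was -0.10. Cyp27a1, which makes 27HC, had -0.07 (SE 0.30). Cyp7b1, which breaks it down, had -0.17 (SE 0.33), and Ch25h, which makes another oxysterol, had -0.53 (SE 0.19). The oestrogen receptor gene Esr1 had 5.55 ± 1.04 CPM (SD, n = 9) and 5.61 ± 1.75 CPM (SD, n = 10), and 9 of 15 oestrogen-responsive genes were above 0, with a median of 0.06. None of these 4 lists passed camera with the preset correlation, whose adjusted p values were 0.312, 0.0924, 0.312 and 0.998 in the order given. The cholesterol synthesis list passed, with medians below 0, in 7 of 19 fits that left out 1 tumour (DMSO replicates 1_5 and 2_4, and 27HC replicates 1_1, 1_2, 2_1, 2_4 and 2_5), with adjusted p from 0.000871 to 0.0454. Over the 19 fits the cholesterol synthesis median ran from -0.125 (without DMSO replicate 1_5) to -0.003 (without DMSO replicate 1_1). The liver X receptor median ran from -0.12 (without 27HC replicate 1_5) to -0.01 (without 27HC replicate 1_2). The oxysterol median ran from -0.20 (without 27HC replicate 2_3) to 0.03 (without DMSO replicate 2_3), and the oestrogen median from -0.00 (without DMSO replicate 1_2) to 0.09 (without DMSO replicate 1_4).

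Across the 34 lists, 12 passed camera with the preset correlation, 3 toward higher and 9 toward lower levels with 27HC. With a correlation estimated per list 0 passed, with a smallest adjusted p of 0.196. fry called 0 lists, with a smallest adjusted p of 0.768 for a shared direction and 0.958 for changes in either direction, neither of which compares a list with other genes. The score per tumour differed for 0 lists in the exact permutation test, whose smallest adjusted p was 0.882, and 1 list had an unadjusted p under 0.05. In each of the 34 lists 0 members passed over all genes tested, and 0 passed when adjusted over the list alone, with a smallest adjusted p of 0.0565 for Pdk1. In what follows a list's adjusted p is that of camera with the preset correlation unless it says otherwise.

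Immune and inflammatory lists made up several of those on the lower side. Of 31 interferon response genes, 28 had a fold change below 0, with a median of -0.20, an adjusted p of 6.82e-10, and an adjusted p of 0.406 with an estimated correlation. Oas1a and Irf7, an antiviral enzyme and a transcription factor of this response, had log2 fold changes of -0.37 (SE 0.18) and -0.31 (SE 0.17). Among 24 inflammatory cytokine genes 20 were below 0 (median -0.19, adjusted p = 2.55e-06, and adjusted p = 0.196 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 had -0.76 (SE 0.24) and -0.47 (SE 0.24), and Arg1, the arginase of alternatively activated macrophages, -1.31 (SE 0.57), which was -0.10 without DMSO replicate 1_3, a tumour far above the other DMSO tumours. All 17 macrophage and monocyte genes were below 0 (median -0.21, adjusted p = 1.86e-05, and adjusted p = 0.406 with an estimated correlation). Adgre1, which encodes F4/80, had -0.31 (SE 0.31) and the complement gene C1qb -0.23 (SE 0.13). Of 22 T and NK cell genes, 19 were below 0 (median -0.21, adjusted p = 1.86e-05, and adjusted p = 0.589 with an estimated correlation). The perforin gene Prf1 had -0.46 (SE 0.31) and Cd8a -0.20 (SE 0.35), or -0.20 and 0.08 without DMSO replicate 2_4. Scores of these lists varied widely between tumours of 1 group: the interferon score was 0.26 ± 0.55 (SD, n = 9) with DMSO and -0.23 ± 0.78 (SD, n = 10) with 27HC, exact permutation p = 0.137. The macrophage call was lost among tumours with first title number 1 alone (median -0.06, adjusted p = 0.0866, against -0.51 and 0.000423 with number 2), and the T and NK call among those with number 2 alone (median -0.33, adjusted p = 0.156). Without 27HC replicate 1_3, 1 of the 5 libraries of low GC content, the medians were -0.36 for interferon, -0.29 for cytokines, -0.45 for macrophages and -0.37 for T and NK cells, and without 27HC replicate 2_3 the latter pair had -0.37 and -0.42. The T and NK median was -0.13 without DMSO replicate 2_4, and the macrophage median was -0.13 without each of DMSO replicates 1_5 and 2_3 and 27HC replicates 1_1 and 1_2. Without all 5 low-GC libraries the medians were -0.30, -0.36, -0.47 and -0.42 in the same order. The mean score of those 5 libraries was above that of the other 14 on these lists, by 0.94, 0.54, 0.64 and 0.75, although 27HC replicate 1_5, 1 of the 5, was below 0 on each (-0.32, -0.22, -0.54 and -0.57). The exact permutation p was 0.0556 for the cytokine score, 0.143 for macrophages and 0.308 for T and NK cells.

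Neutrophil genes, of the cell type from which the vesicles came, went both ways. S100a8, which encodes a subunit of calprotectin, had 12.9 ± 6.38 CPM (SD, n = 9) with DMSO and 24.7 ± 18.5 CPM (SD, n = 10) with 27HC, and its partner S100a9 9.30 ± 5.97 and 14.1 ± 12.1 CPM. Their log2 fold changes were 0.94 (SE 0.38) and 0.61 (SE 0.43), or 0.59 and 0.20 without 27HC replicate 1_5. Retnlg, with 0.85 (SE 0.33), was also above 0, and Csf3r, the receptor of granulocyte colony-stimulating factor, had -0.14 (SE 0.19). Over 17 genes the median was -0.02 and the mean 0.20 (adjusted p = 0.254). B and plasma cell genes had a median of 0.06 and a mean of -0.04 (10 genes, adjusted p = 0.210), with Ighm at -0.59 (SE 0.35). Dendritic cell genes had a median of -0.05 (10 genes, adjusted p = 0.244), which was -0.19 without 27HC replicate 1_3 and -0.02 without 27HC replicate 2_2. Antigen presentation genes of class I (13 genes, median -0.01, adjusted p = 0.668) and class II (10 genes, median -0.09, adjusted p = 0.270) did not pass, with B2m at -0.12 (SE 0.16) and H2-Aa at -0.18 (SE 0.21). Calls appeared when 1 tumour was left out: for neutrophils without DMSO replicate 1_3 (median 0.17, adjusted p = 0.0244) or 27HC replicate 1_3 (0.11, 0.00386), for B and plasma cells without 27HC replicates 1_3, 1_4 or 2_3 (medians -0.16, -0.06 and -0.17, adjusted p from 0.0148 to 0.0488), for class I without 27HC replicate 2_4 (-0.11, 0.0357), and for class II without DMSO replicate 2_1 or 27HC replicate 1_4 (-0.14 and -0.15, 0.0199 and 0.022). Class I had medians of -0.28 with first title number 1 alone and 0.36 with number 2 alone, past the threshold in each. Neutrophils also passed with number 2 alone (0.17, adjusted p = 0.0396), and B and plasma cells with quality weights (-0.43, 0.02).

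**Figure D2:**
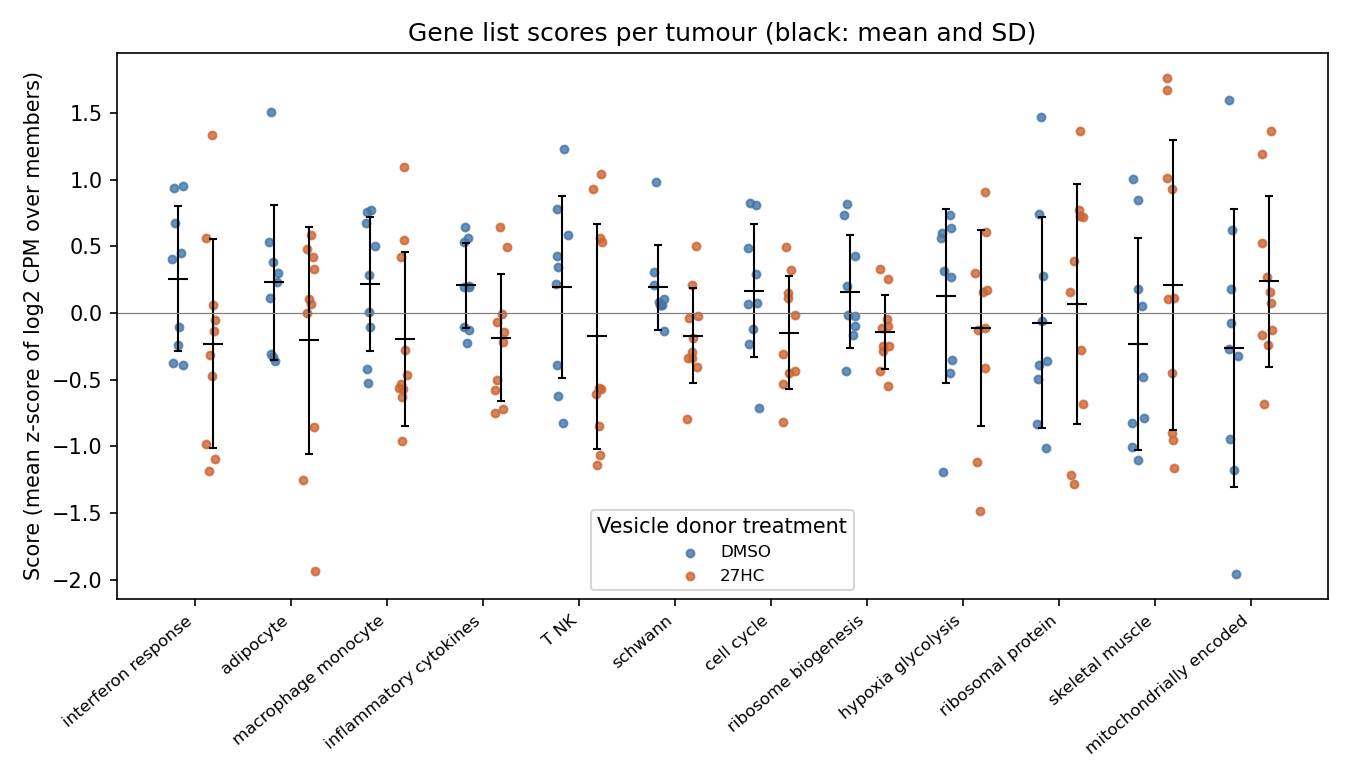
Score of each tumour (vertical axis, mean z-score of log2 CPM over the members) for the 12 lists that passed camera with the preset correlation (horizontal axis, ordered by the difference between the groups). Blue points are 9 DMSO tumours, orange points are 10 27HC tumours, and black marks are mean and SD. The groups overlap in each list, and 0 lists passed the exact permutation test of the score after adjustment.

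Growth programmes held small fold changes, most of them below 0. In the cell cycle list 22 of 30 genes were below 0 (median -0.08, adjusted p = 0.00018, and adjusted p = 0.406 with an estimated correlation). The replication helicase gene Mcm6 and the spindle gene Tpx2 had -0.20 (SE 0.11) and -0.26 (SE 0.15), while the proliferation marker Mki67 had 0.18 (SE 0.41), or -0.09 without 27HC replicate 1_3. Of 17 ribosome biogenesis genes, 15 were below 0 (median -0.13, adjusted p = 0.00164, and adjusted p = 0.196 with an estimated correlation), among them Nop56 at -0.27 (SE 0.13). Among tumours with first title number 1 alone the ribosome biogenesis call was lost and camera placed the cell cycle list on the higher side (adjusted p = 0.60 for each). With number 2 alone the medians were -0.28 (adjusted p = 0.00253) and -0.27 (6.29e-07). The cell cycle median was -0.03 without DMSO replicate 1_3, -0.05 without 27HC replicate 2_1, and between -0.15 and -0.14 without DMSO replicate 1_2 or 27HC replicates 1_2, 1_3 or 1_5, with the call kept in each of these fits. Hypoxia and glycolysis genes were below 0 for 20 of 22 entries (median -0.05, adjusted p = 0.00824, and adjusted p = 0.690 with an estimated correlation). Pgk1 and Ldha, glycolytic enzymes, had -0.27 (SE 0.13) and -0.20 (SE 0.24), and Vegfa, the vascular growth factor, -0.02 (SE 0.12). This last list lost its call in 6 of 19 fits that left out 1 tumour (DMSO replicates 1_2, 1_3, 1_4 and 2_2, and 27HC replicates 1_3 and 2_3), where its adjusted p ran from 0.0699 to 0.44. Over the 19 fits its median ran from -0.03 (without DMSO replicate 2_2) to -0.16 (without DMSO replicate 2_3). It was also lost with quality weights (0.89), without 5 libraries of low GC content (0.491) and with the muscle score as covariate (0.252), and the median was 0.21 with number 2 alone (adjusted p = 0.087) and -0.29 with number 1 alone (2.66e-10).

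Markers of epithelial and mesenchymal state did not pass. Cdh1, which encodes E-cadherin, had 7.76 ± 3.17 CPM (SD, n = 9) and 6.50 ± 2.44 CPM (SD, n = 10), and Vim, which encodes vimentin, 2096 ± 632 and 2178 ± 607 CPM. Their log2 fold changes were -0.26 (SE 0.27) and 0.06 (SE 0.21). The mesenchymal list had 21 of 29 genes above 0 (median 0.13, adjusted p = 0.171), with Col1a1 at 0.37 (SE 0.28). The epithelial list had 14 of 22 above 0, with a median of 0.13 although camera placed it on the lower side (adjusted p = 0.398). The epithelial list turned with the tumours used: its median was -0.48 with first title number 1 alone (adjusted p = 1.05e-09), 0.59 with number 2 alone (0.00793), -0.11 without 27HC replicate 2_2 (0.000324), 0.55 without the 5 low-GC libraries (0.000132) and 0.35 with quality weights (0.0112). The mesenchymal list passed without DMSO replicates 1_4 or 2_2 or 27HC replicate 1_4 (medians 0.18, 0.18 and 0.19, adjusted p from 0.0183 to 0.0434) and with the GC correction (0.10, 0.0424). Over the 19 fits its median was lowest at 0.07, without 27HC replicate 2_3. Axin2, a target of Wnt signalling, had 0.33 (SE 0.16) and Ctnnb1, which encodes beta-catenin, -0.18 (SE 0.11), and the 17 genes of the Wnt list had a median of -0.00 and a mean of 0.06 (adjusted p = 0.602). The p53 targets (15 genes, median 0.05, adjusted p = 0.945), unfolded protein response (17 genes, median -0.06, adjusted p = 0.339) and oxidative phosphorylation genes (25 genes, median 0.03, adjusted p = 0.519) did not pass. Nor did immediate early and heat shock genes (15 genes, median 0.00, mean -0.04, adjusted p = 0.366) or genes of the vesicle-forming machinery (19 entries, median -0.02, adjusted p = 0.783). The unfolded protein response list passed without DMSO replicate 2_3 (median -0.09, adjusted p = 0.0467) and with number 1 alone (-0.05, 0.0133), oxidative phosphorylation without DMSO replicate 1_3 (0.15, 0.0244), and immediate early genes without DMSO replicate 1_5 (-0.11, 0.0289) or 27HC replicate 2_5 (-0.08, 0.0474). Asns, which encodes asparagine synthetase, had -0.39 (SE 0.15), and the stress-induced transcription factor gene Atf3 -0.53 (SE 0.22).

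Skeletal muscle transcripts differed more between tumours than any other list. All 17 muscle genes had a fold change above 0 with 27HC, with a median of 1.90 (adjusted p = 7.41e-09, and adjusted p = 0.430 with an estimated correlation of 0.928). Acta1, skeletal muscle actin, ranged from 0.62 to 424 CPM among DMSO tumours and from 0.81 to 1110 CPM among 27HC tumours, with medians of 7.41 and 62.7. The myosin gene Myh1 and the nebulin gene Neb had log2 fold changes of 2.82 (SE 1.17) and 3.43 (SE 1.10). The median was 0.98 without 27HC replicate 1_5 and 3.45 with first title number 2 alone (adjusted p = 8.21e-18). The score difference had exact permutation p = 0.322, and the median fold change was -0.90 without 5 libraries of low GC content (adjusted p = 0.172), -0.34 with 3 surrogate variables (adjusted p = 0.108) and -0.72 with sample quality weights (adjusted p = 0.246). Fat cell genes went the other way, with 9 of 12 below 0 (median -0.23, adjusted p = 1.86e-05, and adjusted p = 0.406 with an estimated correlation). The adiponectin gene Adipoq had 3.79 ± 3.09 CPM (SD, n = 9) and 1.33 ± 1.16 CPM (SD, n = 10), and Cidea, a lipid droplet protein gene, had a log2 fold change of -2.02 (SE 0.65), or -0.92 without DMSO replicate 1_2. The fat cell call was lost without 27HC replicate 1_3 (adjusted p = 0.0646), without the 5 libraries of low GC content (0.345), with quality weights (0.89) and with first title number 2 alone (0.919, against 7.98e-10 with number 1), and the median was -0.44 without 27HC replicate 1_5.

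Schwann cell genes were below 0 for 6 of 7 (median -0.07, adjusted p = 0.0287, and adjusted p = 0.196 with an estimated correlation), with the myelin genes Mbp and Pmp22 at -0.35 (SE 0.16) and -0.27 (SE 0.13) but Sox10 at 0.43 (SE 0.53). This was the list with the smallest exact permutation p of the score, 0.0285, which was 0.882 after adjustment over 34 lists, and its camera call was lost in 8 of 19 fits that left out 1 tumour (DMSO replicates 1_2, 1_3, 1_4 and 1_5, and 27HC replicates 1_1, 1_3, 1_5 and 2_3), with medians over the 19 fits from -0.05 (without DMSO replicate 1_1) to -0.20 (without 27HC replicate 2_1), adjusted p from 0.0525 to 0.209 where lost, and in other refits with adjusted p up to 0.751, while with first title number 1 alone it was kept (median -0.34, 0.00945). Other stromal lists did not pass: fibroblasts (15 genes, median 0.06, adjusted p = 0.479), endothelium (16 genes, median 0.07, adjusted p = 0.553), and pericytes and smooth muscle (10 genes, median 0.09, adjusted p = 0.366). The endothelial list passed with medians of opposite sign with first title number 1 alone (-0.13, adjusted p = 0.0401) and number 2 alone (0.40, 0.00861), and with quality weights (0.16, 0.0432), and pericytes with number 2 alone (0.06, 0.0396). Pecam1, an endothelial adhesion gene, had -0.08 (SE 0.12) and the fibroblast gene Mfap5 0.37 (SE 0.14). Red cell genes (7 genes, median -0.08, adjusted p = 0.972) and basal epithelial genes (7 genes, median -0.01, mean 0.03, camera on the lower side with adjusted p = 0.398) did not pass either. The red cell list passed with medians of opposite sign without DMSO replicate 1_3 (median 0.72, adjusted p = 0.0244) and without 27HC replicate 1_2 (median -0.71, adjusted p = 0.0392), and the basal list passed without 27HC replicate 2_1 (median -0.09, adjusted p = 0.0374). Red cells also passed with number 2 alone (1.11, 2.77e-05) and the basal list with number 1 alone (-0.57, 0.000124). Lists of gamma delta T cells (4 genes above the filter), milk proteins (3) and keratinocytes (2) were too small to test, and their members summed to a mean of 17.6, 4.56 and 23.5 CPM over all tumours.

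Mitochondrial and ribosomal transcripts, signs of RNA composition, had fold changes mostly above 0. The 13 mitochondrially encoded genes were all above 0 with 27HC (median 0.41, adjusted p = 8.06e-06, and adjusted p = 0.430 with an estimated correlation). They took 5.67 ± 2.36% of counts (SD, n = 9) with DMSO and 6.95 ± 2.19% (SD, n = 10) with 27HC, exact permutation p = 0.237. The mitochondrial median was 0.26 without 27HC replicate 1_2 and 0.24 without 27HC replicate 1_5, and 0.61 with first title number 2 alone. Of 75 ribosomal protein genes 57 were above 0 (median 0.15, adjusted p = 0.00656, and adjusted p = 0.843 with an estimated correlation). Their call was lost in 8 of 19 fits that left out 1 tumour (DMSO replicates 1_5, 2_1, 2_3 and 2_4, and 27HC replicates 1_1, 1_2, 1_5 and 2_4), with adjusted p from 0.0501 to 0.92, and the median ran from 0.03 (without 27HC replicate 1_2) to 0.30 (without DMSO replicate 1_3). Camera placed it on the lower side with first title number 1 alone (adjusted p = 0.657, against a median of 0.36 and 1.52e-08 with number 2) and with 3 surrogate variables (adjusted p = 0.157). The first principal component of the 2000 most variable genes held 38.5% of the variance and set apart 5 libraries, DMSO replicates 1_5 and 2_3 and 27HC replicates 1_3, 1_5 and 2_3. In these libraries genes with GC-rich transcripts were low relative to the other tumours (Spearman's rho across 15406 genes, which are not independent, from -0.67 to -0.55). The component did not separate the treatments (exact permutation p = 0.820).

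**Figure D3:**
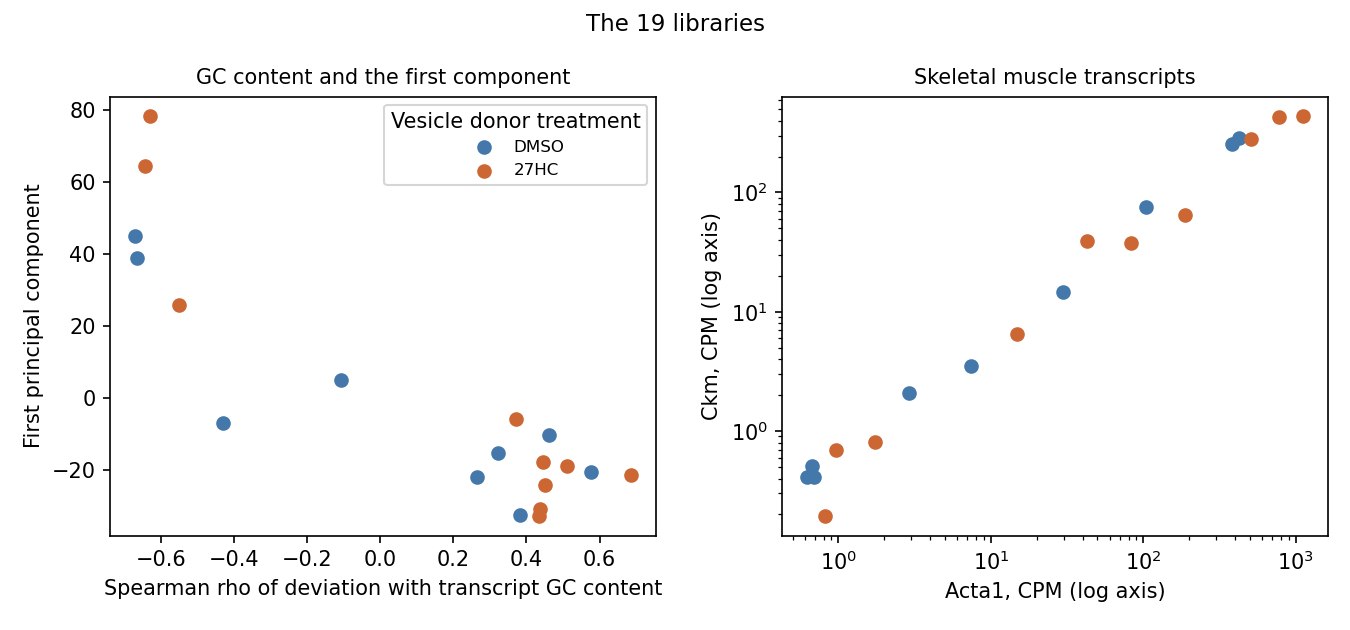
Left, position of each of the 19 libraries on the first principal component (vertical axis) against the Spearman correlation of its log2 deviations with transcript GC content (horizontal axis). Right, CPM of the muscle genes Acta1 and Ckm on log axes. Blue is DMSO, orange is 27HC: 5 libraries with a correlation below -0.5 lie highest on the component, and muscle transcripts are high and low in both groups.

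Tumours whose titles start with a 1 and those with a 2 were compared for a difference in the response. The interaction of treatment with this number passed for 0 of 15629 genes in edgeR's test, with 223 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.911. limma with quality weights also called 0, with 1700 genes at an unadjusted p under 0.05. Tests without any difference would give 781 on average. In edgeR's test, random regroupings of the numbers within treatment gave a median of 227 such genes and at most 3539. The fit with quality weights was not run on regroupings. DESeq2 was not run for the interaction. The strongest contrast between the numbers among the lists was in class I antigen presentation, whose score difference was -0.82 among the first (5 against 5) and 0.85 among the second (5 against 4). A permutation test over all 31752 regroupings of the numbers within treatment, chosen after the data were seen, gave p = 0.00649 for that contrast, which was 0.221 after Benjamini-Hochberg adjustment over 34 lists. In this test 0 lists passed. Among other lists whose medians turned between the numbers, its adjusted p was 0.825 for the epithelial, endothelial and basal lists and 0.874 for red cells.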

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

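No result in this part was weighed against explanations, and the rule that picked them was set in advance. Each value is the highest or lowest tumour of its group and stands farther from its nearest neighbour, relative to the range of the group, than Dixon's 95% limit allows. The rule was applied to 380 groups of values, where chance alone, at about 1 in 20 groups, would pick about 19, and it picked 18, so the number itself is no more than chance gives. Of the 18, 6 belong to DMSO replicate 1_3, 4 to 27HC replicate 1_3 and 3 to DMSO replicate 1_2.

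In DMSO replicate 1_3, in log2 CPM, the sterol regulator gene Insig1 (3.93, next tumour 4.74) and Ctnnb1 (7.98, next 8.41) were the lowest of the group. In the same tumour Arg1 (6.69, group median 2.82) and the ribosomal protein genes Rpl11 (9.29, next 8.48) and Rpl3 (6.01, next 5.23) were the highest, as was the Schwann cell score (0.98, next 0.30). In 27HC replicate 1_3 the Wnt target Lef1 (1.07, next 3.69), the neutrophil granule genes Camp (-2.72, next 0.53) and Ngp (-3.26, next 1.65), and the neutrophil score (-1.15, next -0.28) were the lowest of the group. In DMSO replicate 1_2, Ch25h (4.09, next 3.60) and the fat cell score (1.51, next 0.53) were the highest and Mki67 (4.45, next 6.86) the lowest.

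The collagen gene Col1a2 was lowest in DMSO replicate 1_5 (7.92, next 8.63) and Fos, an immediate early gene, was highest in DMSO replicate 2_1 (6.01, next 4.06). In 27HC replicate 1_5 the respiratory chain gene Ndufa5 (5.02, next 4.02) and Rpl11 (8.69, next 8.30) were highest. The red cell score was highest in 27HC replicate 1_2 (1.97, next 0.48).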

How the results depend on the processing

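The GC correction, the fit without 5 low-GC libraries, the muscle covariate and the surrogate variables were chosen after the data were seen. At an adjusted p under 0.05 the count of genes changed was 0 in edgeR under each alternative fit, and 0 with limma-voom, quality weights and the random block. DESeq2 alone called 2 genes, 1 higher (Tsc22d3, present in all tumours) and 1 lower (Bpifa2). Bpifa2 had 99.9% of its reads in 1 tumour, and at least 10 expected counts in 8 of 9 DMSO and 1 of 10 27HC libraries. Outside that tumour its counts were at most 74.3, in a 27HC library. Genes at an unadjusted p under 0.05 ranged from 164 (first title number 1 alone) to 1267 (3 surrogate variables). Leaving out each tumour in turn gave 0 genes in 19 of 19 fits, with the smallest adjusted p between 0.266 and 1, and between 10 and 15 lists. Fits with 1 to 5 surrogate variables (883 to 1577 genes at an unadjusted p under 0.05) and without 4 libraries (519) also gave 0 genes. At an adjusted p under 0.10 the edgeR fit of treatment alone gave 0 genes and the fit with 5 surrogate variables 1.

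The 12 lists called by camera fell to 0 with an estimated correlation and 0 with fry, and ranged from 9 to 15 in the refits. Interferon response, inflammatory cytokines and mitochondrially encoded genes held their call in 32 of 32 refits, and the other 9 lists lost it in at least 1. Medians were 0.038 for cell cycle and 0.058 for ribosomal protein genes with first title number 1 alone, where camera turned both directions, and 0.21 for hypoxia with number 2 alone. Skeletal muscle turned to -0.72 with quality weights, -0.90 without the 5 low-GC libraries and -0.34 with 3 surrogate variables, where ribosomal protein genes had -0.031. Of the 5 low-GC libraries, 27HC replicates 1_3, 1_5 and 2_3 had muscle scores of 1.67, 1.76 and 0.93. DMSO replicates 1_5 and 2_3 had 0.055 and -0.83. The quality weights of those 27HC replicates were 0.208, 0.466 and 0.257. Both of these refits thus removed or weighted down 27HC tumours with high muscle scores. The cause of the other turns was not tested. The muscle list was not tested with its own score as covariate. Of 22 uncalled lists, 14 passed in at least 1 refit. Leaving out 1 tumour moved the median by over 1.5 times for all 22 and turned its sign for 16. Such a ratio moves easily where the median is near 0: that of the Wnt list, -0.001, ran from -0.053 to 0.043. Among 5280 refitted values of 156 named genes, 173 changed sign, with no call under either setting.

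The full title number is shared by 9 DMSO and 9 27HC tumours but did not pair them: deviations of same-numbered tumours correlated between -0.43 and 0.78, 5 of 9 above 0.1, and 1 of 9 matched its own number best. With it as a block, 0 genes (226 at an unadjusted p under 0.05) and 11 lists passed, among them cholesterol synthesis (adjusted p = 0.0185), while the ribosomal protein (0.131) and Schwann cell lists (0.053) did not. The share of sequencing depth in the width of the intervals was not tested.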

Other observations

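The tests of muscle tissue below, the variants of the glucocorticoid list, the relation of that list to Tsc22d3, the spread of the GC test, the lymphocyte scores of single libraries and the relations between scores were chosen after the data were seen; the other tests were set before their results were known. Across the 19 tumours 6 relations between immune list scores were tested, none of them with the class I, dendritic cell or cytokine lists. The T and NK score followed the interferon response score with Pearson's r = 0.83 (permutation p = 3e-05, 0.00018 after Benjamini-Hochberg adjustment over 6 relations) and Spearman's rho = 0.86 (permutation p = 4e-05). The value of r was 0.81 without the 2 farthest tumours, 0.78 without the 5 low-GC libraries, 0.81 within DMSO and 0.83 within 27HC. The T and NK score also followed B and plasma cells (r = 0.79, permutation p = 0.0001, adjusted 0.0003; rho = 0.77, p = 0.00018; 0.65 without the 5 libraries), macrophages (r = 0.77, permutation p = 0.00037, adjusted 0.00044; rho = 0.73, p = 0.00058; 0.65 without them) and class II genes (r = 0.76, permutation p = 0.00025, adjusted 0.00039; rho = 0.70, p = 0.0013; 0.83 without them). Without the 2 farthest tumours these values were 0.78, 0.74 and 0.79, within DMSO 0.56, 0.66 and 0.67, and within 27HC 0.90, 0.80 and 0.83. Macrophages and the interferon response had r = 0.76 (permutation p = 0.00026, adjusted 0.00039; rho = 0.70, p = 0.0011), 0.69 without the 2 farthest tumours, 0.55 without the 5 libraries, 0.67 within DMSO and 0.75 within 27HC. The neutrophil score did not follow macrophages (r = -0.20, permutation p = 0.41, adjusted 0.41; rho = -0.09, p = 0.70; 0.07 without the 2 farthest, 0.26 without the 5 libraries, 0.14 within DMSO, -0.37 within 27HC). No gene belongs to more than 1 of these lists.

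DMSO replicate 1_5 stood apart in 3 genes that salivary glands are known to express. Bpifa2 had 197017 expected counts there and at most 74.3 in any other tumour. Amy1, salivary amylase, had 78115 against at most 97.2, and Dnase1, a secreted nuclease, 6104 against at most 81.2. These genes were chosen after their values were seen.

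For the counts of 0 genes changed and 0 genes with an interaction, all 100 of 100 splits give as many by construction, so the splits decide nothing about them, and the highest other split gave 1 and 0 genes. As many as 12 lists past camera with the preset correlation came from 37 of 100 splits. The other splits had a median of 10 lists, and the highest gave 21. Chance therefore cannot be excluded for the count of lists. At an unadjusted p under 0.05 the real split gave 354 genes, other splits had a median of 304, and the highest gave 6400, several times the real count, which points to a structure among the tumours apart from treatment.

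Skeletal muscle was the list with the widest spread between tumours of 1 group (SD 2.90 on the log2 scale, against 1.24 for the next, red cells). Whether muscle was part of the structure seen in the splits was not tested. Acta1, Ckm, Myh4, Mylpf, Tnnt3, Tnnc2 and Atp2a1 each followed the mean of the others with r of at least 0.958 within DMSO and 0.973 within 27HC, which is consistent with muscle tissue carried along in some samples. A rise of muscle transcripts as an effect of the 27HC vesicles was not shown (exact permutation p = 0.322), and the log2 difference of 1.26 had a 95% bootstrap interval from -1.19 to 3.72. That effect cannot be told apart from uneven carry-over with 19 tumours.

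The 5 libraries at 1 end of the first component had low GC content correlations. A correction of each library for transcript GC content moved the share of the component from 38.5% to 32.1% and left the same 5 libraries at its end, but the lowest of them stood at 14.01 against 13.01 for the next library, where it had been 25.79 against 5.14. By the rule set in advance this result counted against GC bias, as the share was 0.834 of its first value and the 5 places were kept. The spread of this test was checked after the data were seen. With each library left out in turn the low-GC libraries kept the end in 14 of 19 fits, so GC bias as the cause cannot be excluded. After the correction the mean T and NK score was higher in these 5 samples than in the other 14 by 0.73. Its 95% bootstrap interval was 0.04 to 1.33. The B and plasma cell score was higher by 1.19 (0.35 to 1.82). Both intervals lay above 0, which met the rule set in advance for more lymphocytes. In the check of single libraries, added later, 27HC replicate 1_5 had -0.59 and -0.70, below the medians of the other 14 (-0.51 and -0.44). More lymphocytes thus do not describe all 5 and stay open for the rest, and other lists also had intervals without 0, among them mitochondrially encoded genes (-1.39, -2.01 to -0.62), cholesterol synthesis (-1.03, -1.44 to -0.57), ribosomal protein genes (-0.90, -1.57 to -0.06), muscle (1.06, 0.08 to 1.95), interferon (1.01, 0.39 to 1.58), class II (1.01, 0.20 to 1.79) and macrophages (0.99, 0.36 to 1.56). Before the correction the difference was 0.21 (-0.46 to 0.97) for mitochondrially encoded genes, 0.06 (-0.72 to 0.82) for class II and 0.98 (-0.01 to 1.87) for muscle. The other lists named here had intervals on the same side of 0 before it. The samples were picked by GC content, and no group in the labels separates them.

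Tsc22d3 and Per2, the coding genes with the smallest p on the higher side, are both induced by glucocorticoids, and 16 other glucocorticoid-induced genes were then compared in the same tumours. Their mean log2 level was higher with 27HC by 0.34 (95% bootstrap interval 0.09 to 0.58, two-sided exact permutation p = 0.0205), a p that does not allow for the choice of the hypothesis from these tumours. Of the 16 genes, 12 had a log2 fold change above 0, and the median was 0.21. Within groups the mean followed Tsc22d3 (r = 0.49) but not Per2 (r = -0.12). The difference was 0.02 (exact p = 0.894) with the relation to Tsc22d3 removed and 0.40 (exact p = 0.00791) with that to Per2 removed. As Tsc22d3 is itself induced by glucocorticoids, its removal would take out a real effect as well as a carry-over of that choice. Higher glucocorticoid signalling therefore cannot be told apart from such a carry-over. The difference was 0.22 (exact p = 0.175) with first title number 1 alone and 0.49 (exact p = 0.0556) with number 2 alone, 0.28 (exact p = 0.0512) without Pdk4 and 0.23 (exact p = 0.137) without Zbtb16 as well, and the exact p was 0.106 for the mean z-score, 0.0398 after removing the muscle score, 0.0134 after the GC correction, 0.0309 without the 5 low-GC libraries, and 0.0424 at most when 1 tumour was left out. A difference in clock phase, measured on 13 other clock genes, had a value of 0.15 (interval -0.10 to 0.39, exact p = 0.256), which leaves it open, and handling and time of harvest are not given in the labels. Per1, with a log2 fold change of 0.80 (SE 0.34), belonged to both the glucocorticoid and the clock list, and neither was compared without it.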
